A study of Marchantia polymorpha with 18 samples.

How the data were processed

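RNA was measured in 18 libraries of Marchantia polymorpha: Tak-1, Mpcoi1 and Mpdes6fad5, each after mock treatment and after wounding, with 3 biological replicates per group. Per the labels, plants grew for 3 weeks on half-strength Gamborg B5 medium with 1% agar. The tissue is labelled as leaflets, and the growth protocol names apical fragments free of gemma cups. Wounds were made with tweezers, and each replicate pooled 6 to 8 plants. The treatment label gives 2 h, while the protocol gives freezing at 90 min. RNA was purified on columns with DNase, and a sequencing company prepared the libraries with a standard Illumina protocol. Strand and genome build are not given in the sources used here. Per the submitters' processing notes, reads went through Trim Galore, HISAT2, HTSeq and edgeR, without stated versions.

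The deposited values are in log2 units: log2 CPM with a small prior count, equal to 2.04 reads at the mean effective library size. Every library shared a floor of -3.50, which is 0.0886 CPM. CPM was obtained by raising 2 to each value and subtracting the floor. Above the floor the values were whole multiples of 1 step per library, so read counts were recovered; all values up to 1000 reads were whole numbers within 0.01. Reads in genes numbered 19382332 to 26303510 per library, and 2688 of the 20574 listed genes had no read in any library. With 3 reads as the 95% limit of a count of 0, the detection limit was 0.107 to 0.158 CPM. This limit covers counting error alone, not the spread between plants. The 10 most abundant genes held 4.21% to 5.71% of the reads. Library totals divided by effective sizes ran from 0.906 to 1.10.

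A table of 18 columns was matched to the samples by name, with 0 columns left without a sample. Genes were kept where CPM reached 1 in at least 3 libraries, which left 13220. Values were analysed as log2(CPM + 1) with limma 3.58.1 in R 4.3.3, in a single cell-means model of all 18 libraries without a block, with eBayes and a mean trend. The constant of 1 CPM makes fold changes of weakly expressed genes smaller than their ratios of CPM. Contrasts were the wound response in each genotype, the pairwise differences of these responses, and each mutant against Tak-1 in mock plants. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. In differences of response, larger and smaller refer to the signed log2 value. The share of the Tak-1 response kept in a mutant was the slope through the origin of log2 responses over genes changed at least 2-fold in Tak-1, with a jackknife over libraries. Since those genes were chosen on Tak-1, the slope was also measured on a Tak-1 replicate held out of the choice. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 read the values, and matplotlib 3.10.9 drew the figures.

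Gene names came from a reference table of the MpTak2_v7.1 assembly, used for symbols alone because the build behind the deposited identifiers was unknown. Neighbouring genes were taken from the order of the deposited identifiers. Of the identifiers, 17641 matched and 2933 did not, 897 of the latter with a letter suffix; 3091 had a symbol. Of the tested genes, 12752 matched and 2516 had a symbol. The 32 gene lists, the contrasts, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Because the table gave symbols without products, 27 lists were translated into symbol patterns after the symbols were read and before any expression test. The lists for beta-oxidation, photosynthesis, cytosolic ribosomal proteins, rhizoids and organelle-encoded genes matched no symbols and were not used here. Lists with at least 5 measured members, 25 in all, were tested with camera at a preset correlation of 0.01, adjusted over 200 tests. Camera with an estimated correlation and fry were alternatives. The list tests rank genes against all others, and 15 genes belonged to 2 lists. Jasmonate signalling and male germline genes, 4 each, were described gene by gene.

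Named genes followed a rule: for each wound response and each difference, genes past the threshold with a functional symbol and with groups that did not overlap (in Tak-1, for a difference), the 10 largest rises and 10 largest falls. For mock contrasts the rule took 6 each way, and from each list up to 4 members with the largest change past the threshold in Tak-1. The targeted genes and MpJAZ were always read. The text cites a part of these genes. Alternatives fixed in advance were constants of 0.1 and 5 CPM, no filter, a mean of at least 5 CPM, median-of-ratios rescaling, quantile normalization, robust eBayes, fits of only the groups compared, a 2-fold minimum, replicate number as a block and leaving out each of the 18 libraries. A count model (edgeR, DESeq2) was also planned but was not run. Added after the data were seen were library totals, the deposited values as they are, and voom on recovered counts. The look at Tak-1 genes that responded less in Mpcoi1, and the relabelling of libraries after removal of each genotype's mean, were also added after the results were seen.

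The steps were tested on simulated data of 12954 genes with the depths and spread of these libraries and 200 changed genes. For the Tak-1 wound response, 64%, 86%, 92% and 98% of genes changed 1.5-, 2-, 4- and 8-fold were called, 50 genes for each fold, with 11 unchanged genes called. For the difference between Mpcoi1 and Tak-1 the shares were 56%, 72%, 88% and 98%, with 8 unchanged genes called. A kept share of 0.5 came back as 0.489. The simulation changed far fewer genes than were called in the data, and its noise was drawn independently for each gene and library. Deviations shared by many genes of 1 library were not simulated, so these rates need not hold for these libraries. Replicates were compared by counting error: the chi-square per gene between replicate pairs ran from 3.50 to 32.7, so that no library repeated another.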

Results

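Transcript levels were measured by RNA sequencing in the liverwort Marchantia polymorpha after wounding. The genotypes were the male wild-type accession Tak-1, the mutant Mpcoi1 of the jasmonate receptor gene, and the double mutant Mpdes6fad5 of 2 fatty acid desaturase genes. Each was sampled after mock treatment and after wounding with tweezers, with 3 biological replicates of 6 to 8 plants per group, 18 libraries in all. The treatment label gives 2 h and the treatment protocol gives freezing after 90 min, so the time after wounding is known only as 1 of these values. Libraries held 19382332 to 26303510 reads in genes, and a gene with no read in a library can have been present at up to 0.107 to 0.158 CPM, depending on the library. Of 20574 genes listed, 13220 were tested. The first principal component, with 58.8% of the variance, separated wounded from mock libraries, and the second, with 18.4%, separated Mpdes6fad5 from the other genotypes. Wounded Tak-1 replicate 3 stood apart from its mates, with Pearson correlations of 0.986 and 0.988 against 0.995 between the other wounded Tak-1 libraries. Changes are given as log2 fold changes of CPM + 1 with their standard error from limma, and levels as mean CPM ± SD, with n = 3 libraries per group. Each gene cited among the largest changes of a wound response or of a mock comparison had all 3 libraries of one group above all 3 of the other.

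The genes targeted in the mutants were read first. MpCOI1 (Mp2g26590), the F-box receptor of the jasmonate pathway, stood at 87.6 ± 3.41 CPM in mock Tak-1 and 25.1 ± 1.76 CPM in mock Mpcoi1, a difference of -1.77 ± 0.08 (adjusted p = 2.66e-10). In Mpdes6fad5 its mock level was 79.7 ± 0.896 CPM. MpDES6 (Mp6g17330) was lower in mock Mpdes6fad5 than in mock Tak-1, at 46.3 ± 2.50 against 68.4 ± 7.42 CPM (-0.55 ± 0.11, adjusted p = 9.51e-04). MpFAD5 (Mp3g10660) was lower as well, at 285 ± 28.7 against 467 ± 38.5 CPM (-0.71 ± 0.09, adjusted p = 7.79e-06). After wounding, MpDES6 fell in Tak-1, Mpcoi1 and Mpdes6fad5, by log2 values of -0.73 ± 0.11, -0.56 ± 0.11 and -0.58 ± 0.11. MpFAD5 fell in Mpcoi1 (-0.43 ± 0.09), a response that differed from that of Tak-1 by -0.64 ± 0.13 (adjusted p = 0.00271). Transcripts of all 3 targeted genes were still present in the mutants. The kind of mutation is not given in the sources used here, and a transcript level need not show a lesion. MpJAZ (Mp6g06230), the JAZ repressor of the pathway, served as a marker of its activity. It rose after wounding from 27.6 ± 3.52 to 174 ± 18.7 CPM in Tak-1 and from 18.8 ± 1.22 to 119.7 ± 2.40 CPM in Mpdes6fad5, but only from 17.3 ± 1.29 to 25.8 ± 1.40 CPM in Mpcoi1.

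**Figure D1:**
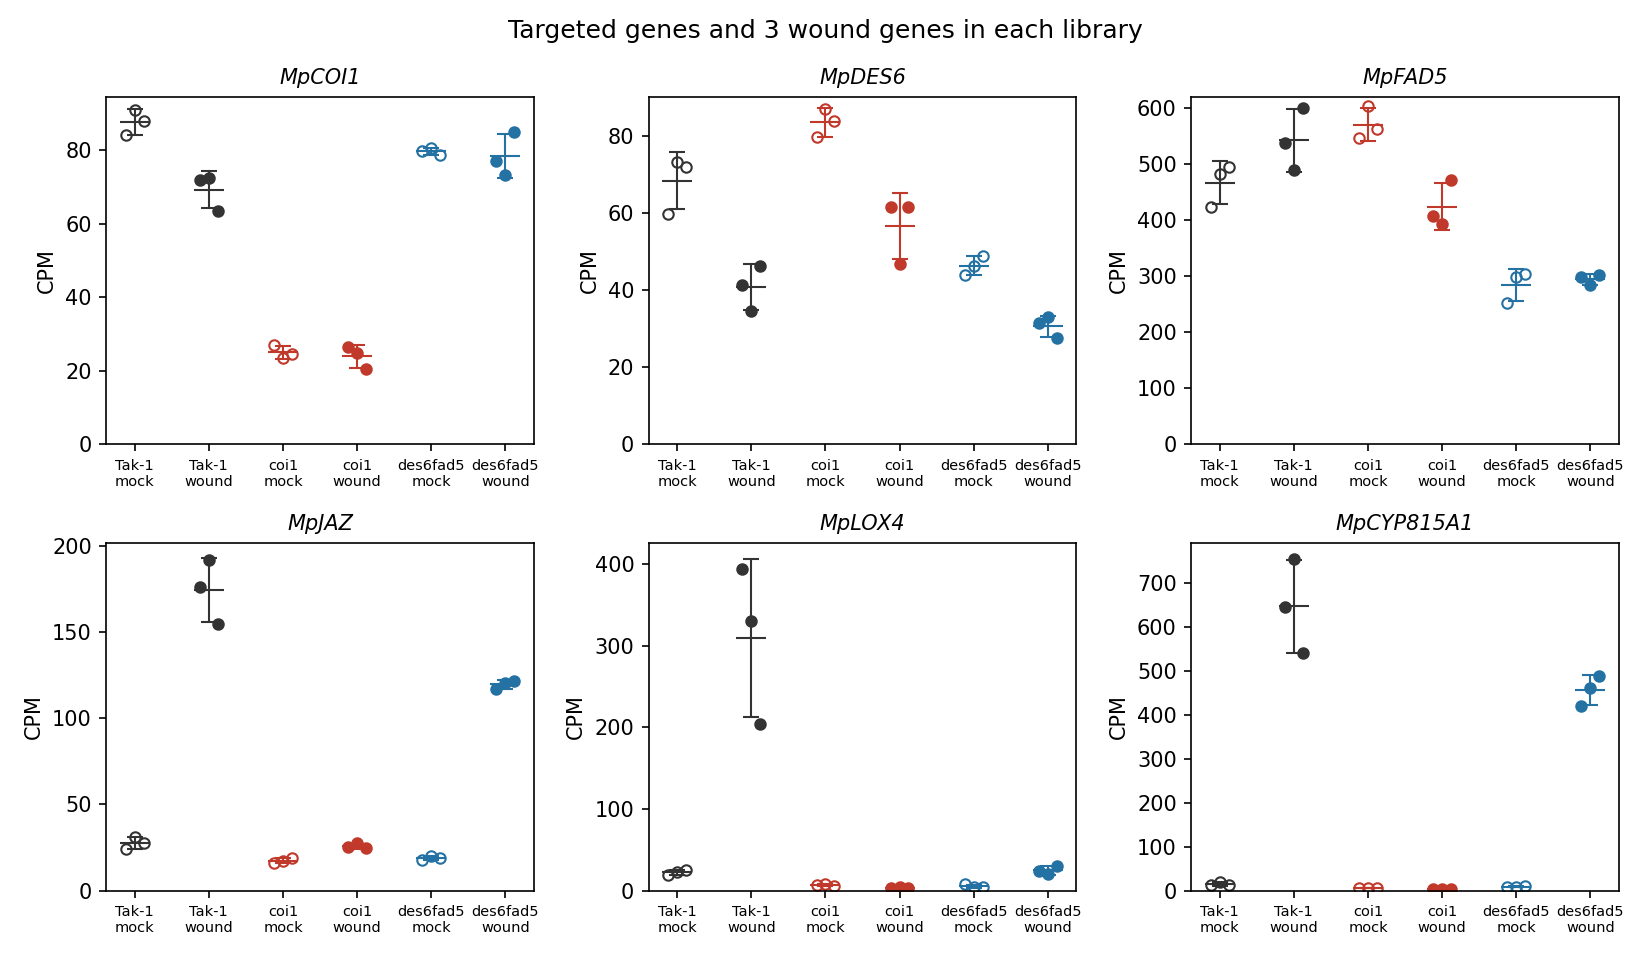
CPM of each library for the genes targeted in the mutants and for MpJAZ, MpLOX4 and MpCYP815A1, in mock and wounded plants. Bars give the mean ± SD of 3 libraries.

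Wounding of wild-type plants was followed by rises of most WRKY genes and of most desiccation genes. Genes of oxylipin, phenylpropanoid and glutathione metabolism went both ways. Genes for class III peroxidases and cell wall enzymes mostly fell, and cell cycle and histone genes fell more often than they rose. In Tak-1, 3439 genes rose and 4041 fell (limma, Benjamini-Hochberg), and 1198 and 364 of these changed at least 2-fold. All 3 wounded libraries lay on one side of all 3 mock libraries for 6903 of the called genes, and for 57.8% of the tested genes, against 10% by chance. Rises made up 46.0% of the calls, but 35.0% with scaling by library totals and 35.9% with quantile normalization, and 50.3% with median-of-ratios rescaling. Library totals and quantile normalization put the median response of all genes at -0.15 and -0.14, against -0.06 as deposited.

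Large rises and falls are named here from the 1477 called genes that had a functional symbol and groups that did not overlap, so genes without a symbol are left out. MpERF21 (Mp5g22160), of the AP2/ERF family, went from 0.723 ± 0.280 to 341 ± 14.8 CPM (7.65 ± 0.12, adjusted p = 2.76e-18). MpBHLH51 (Mp8g06230) rose by 6.98 ± 0.19 and MpBHLH4 (Mp2g00930) by 6.22 ± 0.46, the latter from 4.54 ± 6.35 CPM in mock libraries that differed widely. The dirigent gene MpDIR39 (Mp5g16510) rose by 6.36 ± 0.16, and the cytochrome P450 gene MpCYP815A1 (Mp1g15990) by 5.36 ± 0.16, reaching 647 ± 107 CPM. MpERF9 (Mp4g17430), MpERF15 (Mp7g09350) and MpGST38 (Mp2g03760), a glutathione transferase gene, followed with 4.94, 4.77 and 4.70. Among the falls, MpPOD99 (Mp5g13710) went from 13.4 ± 3.08 to 1.81 ± 0.949 CPM (-2.38 ± 0.19). MpPOD61 (Mp5g02600), MpPOD94 (Mp5g12120) and MpPOD71 (Mp5g04290) fell with -2.12, -2.06 and -2.03. MpYUC2 (Mp8g08780), of the flavin monooxygenases that make auxin, fell with -1.93 ± 0.12, and the transporter gene MpNPF9 (Mp3g09240) with -1.89 ± 0.18.

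Fixed gene lists were counted for transcription factors and signalling. Of 13 WRKY genes measured, 10 rose, 1 fell and 2 did not pass (11 and 1 adjusted over the list alone), with a median of 1.07 (camera, adjusted p = 3.71e-05). MpWRKY10 (Mp7g06550), MpWRKY9 (Mp7g17200) and MpWRKY12 (Mp4g00200) rose by 3.31 ± 0.16, 2.76 ± 0.12 and 2.22 ± 0.07. The WRKY calls of the 3 wound responses, and 1 call for lipoxygenases given for Mpcoi1, were the only 4 of 43 list calls that held with an estimated correlation. Of 19 AP2/ERF genes, 9 rose, 6 fell and 4 did not pass (9 and 6 adjusted over the list alone); the list's test gave adjusted p = 0.0380, and adjusted p = 0.517 with an estimated correlation, and its call was lost with a constant of 0.1 CPM (adjusted p = 0.0549), with deposited values (adjusted p = 0.0544), with voom (adjusted p = 0.0550), and without mock replicate 1 (adjusted p = 0.0554) or wounded replicate 2 (adjusted p = 0.0535) of Tak-1. Of 49 genes of the MAP kinase cascade and phosphatases 2C, 25 rose, 8 fell and 16 did not pass (26 and 8 adjusted over the list alone, adjusted p = 0.00584, and adjusted p = 0.546 with an estimated correlation), with MpMAPKKK10 (Mp4g08320) and MpPP2C_G (Mp6g03430) up by 3.02 and 2.91. With quantile normalization this call was lost (adjusted p = 0.0804), and the list's median went from 0.22 to 0.019. NAC and GRAS genes gave 11 rises and 4 falls among 20 (11 and 4 adjusted over the list alone), with MpGRAS7 (Mp8g01770) at 3.75 and MpNAC3 (Mp4g11910) at 2.40. Among 38 bHLH genes, 14 rose, 11 fell and 13 did not pass (15 and 11 adjusted over the list alone), and the mean of 0.60 differed in sign from the median of -0.016. MYB genes counted 14 rises and 6 falls among 43 (14 and 5 adjusted over the list alone), and C2H2 zinc finger genes 5 and 4 among 21, with MpC2H2-13 (Mp3g09820) at 2.79.

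Of 69 desiccation and abscisic acid genes, mostly for late embryogenesis abundant (LEA) proteins, 42 rose, 11 fell and 16 did not pass (42 and 11 adjusted over the list alone, adjusted p = 3.59e-05, and adjusted p = 0.610 with an estimated correlation). MpLEA-like18 (Mp4g05730), MpLEA-like14 (Mp3g08260) and MpLEA-like59 (Mp8g07630) rose by 3.98 ± 0.19, 3.81 ± 0.33 and 3.43 ± 0.16. Oxylipin genes went both ways: of 17 lipoxygenase and CYP74 genes, 6 rose, 6 fell and 5 did not pass (6 and 6 adjusted over the list alone). MpLOX4 (Mp5g21680) rose from 22.4 ± 3.27 to 309.6 ± 96.8 CPM (3.69 ± 0.23), MpLOX2 (Mp2g23380) by 2.45 ± 0.11 and MpCYP74N2 (Mp5g16260) by 1.77 ± 0.07. Of 66 phenylpropanoid and flavonoid genes, 25 rose, 23 fell and 18 did not pass (26 and 23 adjusted over the list alone), with Mp4CL1 (Mp1g27780), a 4-coumarate-CoA ligase gene, at 4.20 ± 0.06. Of 82 dirigent and polyphenol oxidase genes, 30 rose, 26 fell and 26 did not pass (31 and 28 adjusted over the list alone), and MpPPO22 (Mp5g18380) rose by 2.42 ± 0.22. The polyphenol oxidase gene MpPPO31 (Mp3g24060) went from 0.256 ± 0.244 to 22.9 ± 8.06 CPM. Glutathione and redox genes counted 23 rises and 17 falls among 62 (23 and 17 adjusted over the list alone), with MpGST30 (Mp2g22410) at 3.61 and MpSOD3 (Mp5g07660) at 2.24. Of 119 cytochrome P450 and glycosyltransferase genes, 28 rose, 50 fell and 41 did not pass (29 and 50 adjusted over the list alone), the median of -0.24 and the mean of 0.029 differing in sign. Desaturase and elongase genes gave 8 rises and 8 falls among 22, and terpenoid genes 8 and 13 among 42. MpFAD4 (Mp3g06040) rose by 2.06 ± 0.10.

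The list that moved furthest down was that of class III peroxidases, of which 4 rose, 95 fell and 22 did not pass (7 and 96 adjusted over the list alone) among 121 measured, with a median of -0.90 (adjusted p = 6.45e-10, and adjusted p = 0.274 with an estimated correlation). Of 83 cell wall remodelling genes, 14 rose, 45 fell and 24 did not pass (14 and 45 adjusted over the list alone, adjusted p = 0.0108, and adjusted p = 0.510 with an estimated correlation), a call lost with a mean of at least 5 CPM (adjusted p = 0.0742). MpExpansin11 (Mp2g18600) fell with -1.79 ± 0.13, while MpGH16.7 (Mp2g17810) and the pectin methylesterase gene MpCE8.8 (Mp3g15910) rose by 4.10 ± 0.15 and 3.77 ± 0.15. Of 39 cell cycle and histone genes, 1 rose, 15 fell and 23 did not pass (1 and 14 adjusted over the list alone, adjusted p = 0.0165, and adjusted p = 0.777 with an estimated correlation), with MpH1 (Mp6g03150) and MpH4e (Mp5g16840) at -0.93 and -0.87. Pathogenesis-related and defence genes counted 9 rises and 20 falls among 62. MpPR15c (Mp2g01620) and the glucanase gene MpGH17.15 (Mp6g00360) were among the rises, with 3.82 and 2.36. Receptor-like kinases gave 31 and 29 among 81, auxin genes 12 and 11 among 31, and clock and light genes 7 and 7 among 19. Heat shock genes gave 4 rises and no fall among 6, and calcium signalling genes 5 and 2 among 9. In the jasmonate signalling list of 4 genes, MpCOI1 fell and MpJAZ and MpNINJA (Mp1g04410) rose by 2.62 ± 0.09 and 0.76 ± 0.08. The rise of MpTPL (Mp7g17410), at 0.22 ± 0.07, was not called without mock replicate 1 (log2 0.16) or wounded replicate 2 (log2 0.16) of Tak-1, nor with library totals (0.11) or quantile normalization (0.0012). Lists for other cell types were expressed here too: of 4 male germline genes MpDUO1 (Mp1g13010) rose by 1.56 ± 0.21 and MpGEX2 (Mp4g06790) fell with -0.55 ± 0.13, and of 5 oil body genes 1 rose and 3 fell. Counts given here without a second pair of values were equal when adjusted over the list alone, except those of auxin genes (12 and 12) and of the male germline (2 and 1).

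Most of the wound response was present in the receptor mutant, but part of the genes induced in Tak-1 responded less there. In Mpcoi1, 3234 genes rose and 3765 fell, of which 2605 and 2887 were called in the same direction in Tak-1, against 841 and 1151 expected for independent sets of these sizes. Of the 1198 genes that rose at least 2-fold in Tak-1, 1014 rose in Mpcoi1, 147 did not pass and 37 fell. The response of 333 of them was smaller in Mpcoi1 than in Tak-1, and that of 57 was larger. Of the 364 falls, 346 also fell in Mpcoi1. The slope of the Mpcoi1 responses on the Tak-1 responses over these 1562 genes was 0.754 ± 0.0184 (jackknife SE), with 0.739 for rises and 0.881 for falls. With genes chosen on 2 Tak-1 replicates and measured on the third, it was 0.785, with 0.760 for rises and 1.02 for falls. A shortfall from Tak-1 among the falls was thus not seen on replicates held out of the choice of genes, whereas that among the rises remained. The median share kept per gene was 0.890 ± 0.0312 in Mpcoi1 and 0.893 ± 0.0337 in Mpdes6fad5, nearly equal, whereas the slope gives more weight to genes with large responses.

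Genes that rose steeply in Mpcoi1 included MpERF21, which had the largest rise of the named genes in Tak-1. It rose by 7.39 ± 0.12 in Mpcoi1, MpERF9 by 5.36 ± 0.14, MpGST38 by 5.37 ± 0.13, MpWRKY10 by 3.22 ± 0.16 and MpGH16.7 by 3.97 ± 0.15. Of the WRKY genes, 11 rose, 0 fell and 2 did not pass (11 and 0 adjusted over the list alone), with a median of 1.09 (adjusted p = 4.57e-06). Peroxidases again mostly fell, 88 of 121, with 4 rises (92 and 6 adjusted over the list alone, adjusted p = 1.22e-10, and adjusted p = 0.274 with an estimated correlation). Of the cell wall genes, 12 rose, 49 fell and 22 did not pass (13 and 51 adjusted over the list alone, adjusted p = 5.06e-04, and adjusted p = 0.274 with an estimated correlation). Of the desiccation genes, 44 rose, 9 fell and 16 did not pass (44 and 9 adjusted over the list alone, adjusted p = 1.34e-07, and adjusted p = 0.510 with an estimated correlation). MAP kinase and phosphatase 2C genes gave 24 rises and 6 falls (24 and 7 adjusted over the list alone, adjusted p = 0.00346, and adjusted p = 0.519 with an estimated correlation). Glutathione genes counted 23 rises and 14 falls (23 and 14 adjusted over the list alone, adjusted p = 0.0254, and adjusted p = 0.657 with an estimated correlation), but their median of 0.042 became -0.03 with library totals and -0.06 with quantile normalization, which ended the call (adjusted p = 0.0541). Steep falls in Mpcoi1 were those of MpGH16.30 (Mp4g00700), MpPOD92 (Mp5g10750) and MpLOX12 (Mp8g01650), at -2.85 ± 0.23, -2.52 ± 0.18 and -2.11 ± 0.18.

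The test of the difference between the responses of Mpcoi1 and Tak-1 called 1001 genes, 684 with a smaller and 317 with a larger log2 response in Mpcoi1. Larger responses were 31.7% of them, but 41.9% with quantile normalization. The lipoxygenase and CYP74 list was the one whose call held with an estimated correlation: 0 were larger, 8 smaller and 9 did not pass (0 and 10 adjusted over the list alone), with a median difference of -0.75 (adjusted p = 1.03e-09, and 0.0185 with an estimated correlation). MpLOX4 went from 6.79 ± 0.903 to 3.68 ± 1.04 CPM in Mpcoi1, a difference from Tak-1 of -4.44 ± 0.33 (adjusted p = 2.74e-08). MpLOX2, MpLOX8 (Mp2g12220) and MpCYP74N2 differed by -2.02 ± 0.16, -2.03 ± 0.31 and -2.44 ± 0.10. MpCYP815A1 did not rise in Mpcoi1, at 5.17 ± 0.515 and 3.06 ± 0.787 CPM (difference -5.98 ± 0.23, adjusted p = 3.37e-12). Of the bHLH genes, 0 were larger, 10 smaller and 28 did not pass (3 and 11 adjusted over the list alone, adjusted p = 0.00166, and adjusted p = 0.410 with an estimated correlation). MpBHLH4 stayed near the detection limit in Mpcoi1, at 0.157 ± 0.0954 and 0.115 ± 0.108 CPM, and MpBHLH2 (Mp2g00890), MpBHLH3 (Mp2g00910) and MpBHLH51 differed in response by -2.91 ± 0.13, -3.04 ± 0.31 and -3.03 ± 0.27. MpGH3A (Mp6g07600), of the acyl amido synthetases, differed by -3.91 ± 0.19 and MpCYP94-like (Mp2g10330) by -3.44 ± 0.19. The JAZ gene differed by -2.07 ± 0.13 (adjusted p = 1.79e-09).

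Part of the genes for enzymes of phenolic metabolism and of the P450 genes also responded less in Mpcoi1. Of the cytochrome P450 and glycosyltransferase genes, 3 were larger, 14 smaller and 102 did not pass (3 and 15 adjusted over the list alone, adjusted p = 0.0702, and adjusted p = 0.554 with an estimated correlation), and the list was not called. Of the dirigent and polyphenol oxidase genes, 2 were larger, 16 smaller and 64 did not pass (4 and 18 adjusted over the list alone, adjusted p = 2.20e-07, and adjusted p = 0.270 with an estimated correlation). MpDIR39 rose by 0.56 ± 0.16 in Mpcoi1, a difference of -5.80 ± 0.22, and MpPPO22 fell there with -1.56 ± 0.22. MpPPO31, MpDIR61 (Mp5g16460) and MpDIR65 (Mp5g16440) had no read in any Mpcoi1 library, where a count of 0 allows up to 0.113 to 0.133 CPM, while they reached 22.9 ± 8.06, 14.2 ± 2.70 and 9.20 ± 1.98 CPM in wounded Tak-1. Near-identical neighbouring copies in these families can share reads, so single members are less certain than the group. Phenylpropanoid genes gave 2 larger and 6 smaller responses (2 and 7 adjusted over the list alone, adjusted p = 0.0234, and adjusted p = 0.510 with an estimated correlation). Their call was lost with voom (adjusted p = 0.0513) and without mock replicate 3 (adjusted p = 0.0586) or wounded replicate 3 (adjusted p = 0.0995) of Tak-1. Among them, Mp4CL2 (Mp1g05060) differed by -3.18 ± 0.12 and MpPKS/CHS21 (Mp7g14930) by -2.24 ± 0.59. MpPR15c differed by -3.79 ± 0.31, MpERF7 (Mp6g04880) by -2.14 ± 0.15 and MpGRAS7 by -1.64 ± 0.27. Larger responses were fewer: MpPOD18 (Mp2g20950) by 1.90 ± 0.25, MpPPO38 (Mp6g17770) by 1.56 ± 0.23, MpLEA-like37 (Mp6g03000) by 1.49 ± 0.32 and MpCAT1 (Mp7g09020), a catalase gene, by 1.03 ± 0.15. MpPOD18 reached similar levels in wounded Tak-1 (13.3 to 15.5 CPM) and wounded Mpcoi1 (11.9 to 17.1 CPM). Its larger response came from a lower mock level in Mpcoi1, 0.604 to 1.54 against 5.49 to 6.67 CPM. MpPPO38 stood at 18.1 to 22.7 CPM in mock Tak-1 libraries and at 4.28 to 6.78 CPM in wounded ones. In Mpcoi1 it stood at 0.447 to 0.500 and 0.133 to 0.384 CPM, so its larger log2 response was a smaller fall from a low level, not a rise. The call of MpPPO38 was lost with a constant of 0.1 CPM, with deposited values (log2 1.17) and with voom (1.01), and that of MpLEA-like37 with voom (2.28). Of the desiccation genes, 9 were larger, 5 smaller and 55 did not pass (18 and 5 adjusted over the list alone, adjusted p = 0.0108, and adjusted p = 0.787 with an estimated correlation), a call also lost with voom (adjusted p = 0.178) and with fry (adjusted p = 0.191), in a range of 0.00138 to 0.787 over all alternatives. The WRKY list was not called for a difference (adjusted p = 0.872).

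**Figure D2:**
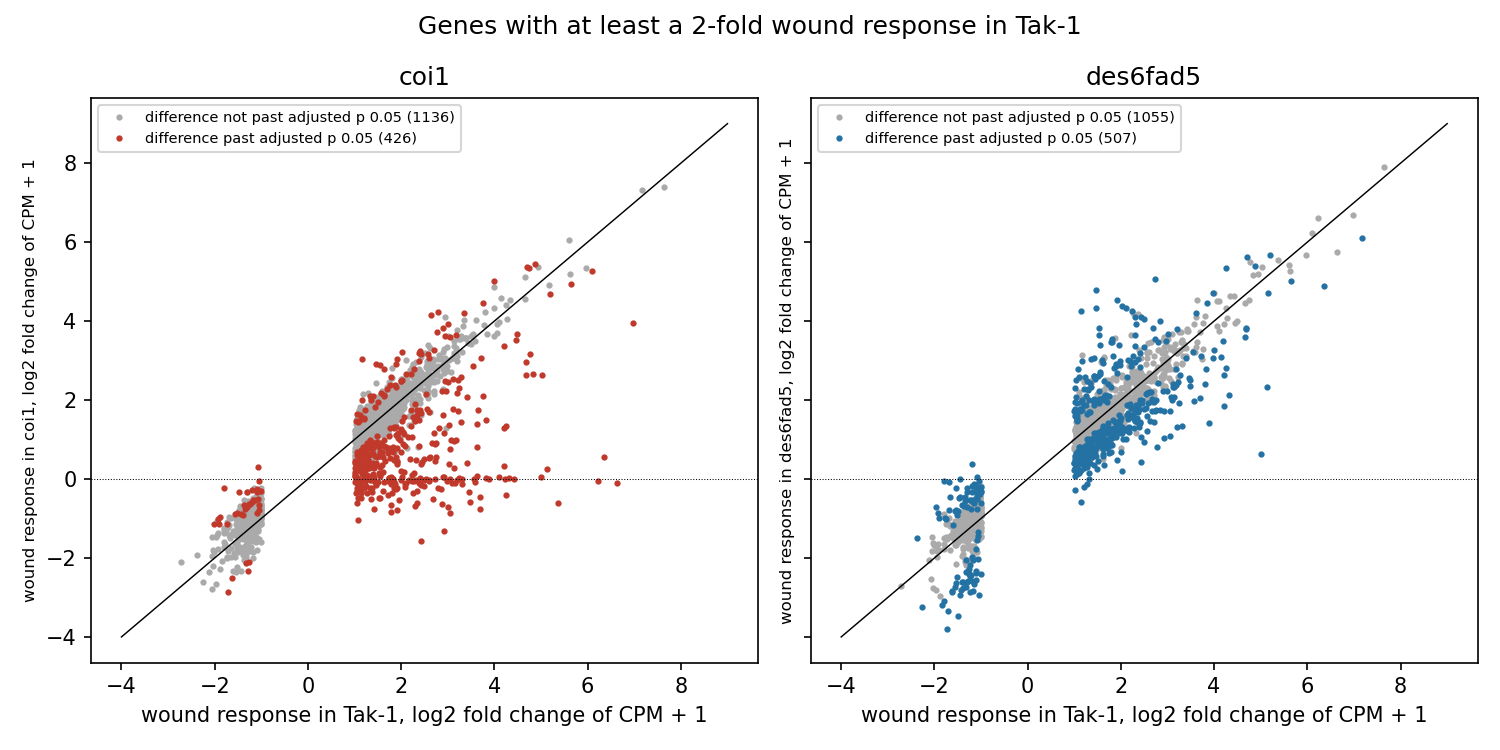
Wound responses in each mutant against Tak-1 for the 1562 genes changed at least 2-fold in Tak-1, as log2 fold changes of CPM + 1. Coloured points are genes whose response differed from that in Tak-1, and the line marks equal responses.

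The desaturase double mutant showed most of the wild-type rises after wounding, the JAZ marker included. Several lipoxygenase genes and single dirigent genes responded less than in Tak-1. In Mpdes6fad5, 3716 genes rose and 3817 fell, and 2711 and 2722 of these were called in the same direction in Tak-1, against 967 and 1167 expected for independent sets. Rises were 49.3% of the calls, but 37.6% with library totals and 35.2% with quantile normalization. Of the 1198 rises of at least 2-fold in Tak-1, 1169 rose in Mpdes6fad5 and 29 did not pass. The response was smaller than in Tak-1 for 293 of them and larger for 117. Of the 364 falls, 341 also fell. The slope on the Tak-1 responses, in which large responses weigh most, was 0.939 ± 0.0246, or 0.975 with genes chosen on 2 replicates and measured on the third. Of the 1356 genes that rose at least 2-fold in Mpdes6fad5, 1183 were called as rising in Tak-1. Wounded Mpdes6fad5 had reads for 16121 ± 71.1 genes per library, against 15796 ± 68.1 in wounded Tak-1.

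Several genes with a smaller response in Mpcoi1 responded strongly in the double mutant. MpJAZ rose by 2.61 ± 0.09, a difference from Tak-1 of -0.01 ± 0.13 (adjusted p = 0.979), MpCYP815A1 by 5.54 ± 0.16 and MpBHLH4 by 6.62 ± 0.46. MpGH3A rose by 2.77 ± 0.13 and MpCYP94-like by 2.94 ± 0.14. Of the WRKY genes, 11 rose, 1 fell and 1 did not pass (12 and 1 adjusted over the list alone), with a median of 1.49 (adjusted p = 1.41e-05), and MpWRKY6 (Mp1g08960) rose by 3.46 ± 0.24. Peroxidases gave 8 rises and 88 falls (8 and 89 adjusted over the list alone, adjusted p = 1.41e-11, and adjusted p = 0.270 with an estimated correlation), and MpPOD19 (Mp2g24530) fell with -3.80 ± 0.24. Of the cell wall genes, 15 rose, 53 fell and 15 did not pass (15 and 53 adjusted over the list alone, adjusted p = 3.40e-04, and adjusted p = 0.274 with an estimated correlation), a call lost with a mean of at least 5 CPM (adjusted p = 0.0522). NAC and GRAS genes gave 12 rises and 4 falls (12 and 5 adjusted over the list alone, adjusted p = 0.0412, and adjusted p = 0.510 with an estimated correlation), a call lost without wounded Mpdes6fad5 replicate 2 (adjusted p = 0.0529). Of the desiccation genes, 51 rose, 6 fell and 12 did not pass (51 and 6 adjusted over the list alone, adjusted p = 4.11e-09, and adjusted p = 0.510 with an estimated correlation).

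The test of the difference from Tak-1 called 1961 genes, 987 larger and 974 smaller in Mpdes6fad5. Larger responses were 50.3% of these, but 40.2% with median-of-ratios rescaling. Of the lipoxygenase and CYP74 genes, 0 were larger, 7 smaller and 10 did not pass (0 and 7 adjusted over the list alone), with a median difference of -0.53 (adjusted p = 0.00415, and adjusted p = 0.270 with an estimated correlation). MpLOX4 went from 5.27 ± 1.90 to 24.6 ± 5.50 CPM, a difference of -1.64 ± 0.33 (adjusted p = 0.00308), and MpLOX8 differed by -1.31 ± 0.31. MpDIR39 differed by -1.47 ± 0.22. MpPPO31, MpDIR61 and MpDIR65 reached 5.34 ± 1.28, 1.84 ± 0.787 and 1.74 ± 1.12 CPM in wounded Mpdes6fad5, below their Tak-1 levels. MpCupin36 (Mp2g05450) differed by -2.43 ± 0.32, MpPOD19 by -2.08 ± 0.34 and MpGH16.30 by -1.63 ± 0.33, all of which fell in the double mutant. Their falls there began from higher mock levels. MpCupin36 stood at 4.61 to 10.1 CPM in mock Mpdes6fad5 libraries and at 0.362 to 0.481 CPM in mock Tak-1, where little fall was possible. For MpPOD19 the mock levels were 18.8 to 36.0 against 2.85 to 3.57 CPM, and for MpGH16.30 15.9 to 28.6 against 7.74 to 11.6 CPM. The MpPOD19 difference was not called with a constant of 0.1 CPM (-1.24), with deposited values (-1.18) or with voom (-0.38). With voom those of MpCupin36 (-3.64), MpDIR61 (-3.06) and MpDIR65 (-2.45) were not called either, at folds no smaller than with limma on log2 values, and that of MpPPO31 changed sign, to 0.99. The MpPPO31 difference was not called with a constant of 0.1 CPM (-0.56) or with deposited values (-0.47) either.

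Larger responses in Mpdes6fad5 included that of a kinase gene. Those of a WRKY gene and of several LEA genes were called with limma on log2(CPM + 1), but were lost or changed sign with voom. MpMAPKKK6 (Mp2g17410) went from 0.587 ± 0.219 to 29.3 ± 5.88 CPM in the double mutant and from 0.348 ± 0.259 to 2.07 ± 1.11 CPM in Tak-1 (3.10 ± 0.36, adjusted p = 2.79e-05). MpWRKY6 differed by 1.68 ± 0.34 and MpPPO38 by 1.76 ± 0.23. MpPPO38 stood at 18.1 to 22.7 CPM in mock Tak-1 libraries and at 4.28 to 6.78 CPM in wounded ones. In Mpdes6fad5 it stood at 1.18 to 2.27 and 1.28 to 1.68 CPM, so its larger log2 response was the absence of that fall, not a rise. Of the desiccation genes, 25 were larger, 5 smaller and 39 did not pass (29 and 7 adjusted over the list alone, adjusted p = 6.49e-06, and adjusted p = 0.554 with an estimated correlation). The list's call depended on the constant added before the log: with 0.1 CPM the adjusted p was 0.115, and over all alternatives it ran from 4.33e-10 to 0.554. MpLEA-like28 (Mp4g17570) and MpLEA-like26 (Mp4g14870) differed by 2.12 ± 0.22 and 1.67 ± 0.32. MpLEA-like39 (Mp6g03050) went from no read to 2.77 ± 0.442 CPM in Tak-1 and from 0.226 ± 0.118 to 27.8 ± 4.93 CPM in Mpdes6fad5, and with voom the difference of response changed sign, to -0.072. Those of MpLEA-like34 (Mp6g02970), MpLEA-like36 (Mp6g02990) and MpLEA-like40 (Mp6g03060) changed sign with voom as well, to -1.47, -2.36 and -0.15. With a constant of 0.1 CPM and with deposited values, MpLEA-like34 (0.23 and 0.090) and MpLEA-like40 (0.67 and 0.59) were not called. MpLEA-like36 changed sign there too (-0.61 and -0.76). The calls of MpLEA-like28, MpLEA-like26 and MpWRKY6 were lost with voom, at 1.35, 1.23 and 2.17, and so was that of MpLEA-like27 (Mp4g14880). Over the 57 LEA genes measured, summed CPM went from 1591 ± 69.6 to 2276 ± 128 in Tak-1, from 1376 ± 60 to 2168 ± 178 in Mpcoi1 and from 1505 ± 111 to 3504 ± 400.1 in Mpdes6fad5.

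Compared directly, the mutants differed in dirigent, polyphenol oxidase, phenylpropanoid and bHLH genes, most of the called members responding more in Mpdes6fad5. The difference between the responses of Mpdes6fad5 and Mpcoi1 called 2419 genes, 1344 of them larger in Mpdes6fad5. That was 55.6% of the calls, but 43.4% with quantile normalization, 46.5% with library totals and 47.2% with median-of-ratios rescaling. Dirigent and polyphenol oxidase genes gave 21 larger and 0 smaller responses (28 and 0 adjusted over the list alone, adjusted p = 2.35e-08, and adjusted p = 0.270 with an estimated correlation). Phenylpropanoid genes gave 17 and 2 (21 and 3 adjusted over the list alone, adjusted p = 0.00162, and adjusted p = 0.364 with an estimated correlation), and bHLH genes 10 and 2 (12 and 4 adjusted over the list alone, adjusted p = 0.0105, and adjusted p = 0.510 with an estimated correlation). Lipoxygenase and CYP74 genes gave 5 and 0 (5 and 0 adjusted over the list alone, adjusted p = 0.00726, and adjusted p = 0.270 with an estimated correlation), and glutathione genes 4 and 15 (4 and 21 adjusted over the list alone, adjusted p = 0.0253, and adjusted p = 0.657 with an estimated correlation), the latter not called with quantile normalization (adjusted p = 0.0531). MpBHLH4 responded more in Mpdes6fad5 by 6.67 ± 0.65, MpCYP815A1 by 6.16 ± 0.23, MpDIR39 by 4.33 ± 0.22, MpPKC2 (Mp2g06680) by 3.49 ± 0.37 and MpJAZ by 2.06 ± 0.13. Smaller responses in Mpdes6fad5 were those of MpLEA-like18, MpPOD18 and MpGST26 (Mp5g00690), at -1.78 ± 0.26, -1.78 ± 0.25 and -1.43 ± 0.28. All began from higher mock levels in Mpdes6fad5 than in Mpcoi1. After wounding, MpLEA-like18 was still higher in Mpdes6fad5 (342 to 421 against 146 to 237 CPM), and so was MpGST26 (119 to 128 against 67.0 to 84.8 CPM). MpPOD18 was lower there (7.83 to 9.55 against 11.9 to 17.1 CPM).

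**Figure D3:**
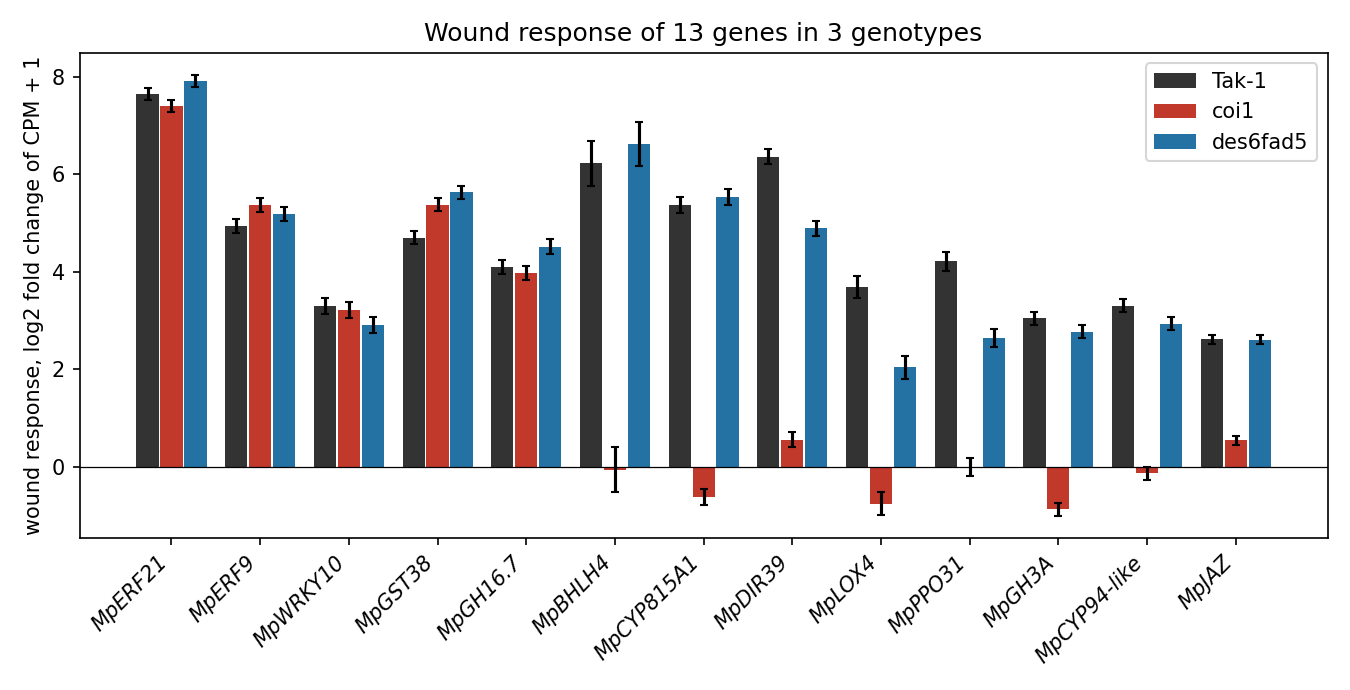
Wound responses of 13 genes in Tak-1, Mpcoi1 and Mpdes6fad5 as log2 fold changes of CPM + 1, with standard errors from limma. MpPPO31 had no read in Mpcoi1.

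Without wounding, the double mutant stood much further from the wild type than the receptor mutant did. In mock Mpcoi1, 278 genes were higher and 603 lower than in mock Tak-1, 136 of them by at least 2-fold. Of the 881 called genes, 871 had groups that did not overlap, as had 29.7% of tested genes, against 10% by chance. Leaving out a library moved this count widely: 419, 1401 and 413 without mock Tak-1 replicates 1, 2 and 3, 546, 363 and 409 without mock Mpcoi1 replicates 1, 2 and 3, and 1407 without wounded Tak-1 replicate 3. MpPOD29 (Mp3g15800), MpPOD28 (Mp3g15790) and MpPOD70 (Mp5g04010) were higher by 2.03 ± 0.25, 2.01 ± 0.17 and 1.98 ± 0.19, and MpGH16.16 (Mp3g10390) by 1.77 ± 0.27. MpPPO38 was lower, at 0.467 ± 0.0292 against 20.7 ± 2.37 CPM (-3.88 ± 0.16, adjusted p = 9.97e-11). The ammonium transporter gene MpAMT2.4 (Mp8g18510) differed by -2.47 ± 0.21, MpPPO40 (Mp6g17740) by -2.41 ± 0.14 and MpKOL3 (Mp2g01940) by -2.20 ± 0.22. Phenylpropanoid genes gave 0 higher and 10 lower (0 and 13 adjusted over the list alone, adjusted p = 3.12e-05, and adjusted p = 0.270 with an estimated correlation). Cytochrome P450 and glycosyltransferase genes gave 1 and 14 (2 and 21 adjusted over the list alone, adjusted p = 0.0124, and adjusted p = 0.497 with an estimated correlation). Pathogenesis-related genes gave 0 and 3 (0 and 2 adjusted over the list alone, adjusted p = 0.00346, and adjusted p = 0.510 with an estimated correlation), a call lost without mock Tak-1 replicate 1 (adjusted p = 0.0705). MpJAZ differed by -0.64 ± 0.09.

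In mock Mpdes6fad5, 2318 genes were higher and 2698 lower, 290 and 280 of them by at least 2-fold, and groups did not overlap for 4848 of the calls. Higher genes were 46.2% of the calls, but 73.8% with scaling by library totals, which put the median difference of all genes at 0.14. The terpene synthase-like gene MpMTPSL23 (Mp4g19090) was at 30.3 ± 0.136 against 0.135 ± 0.0756 CPM (4.79 ± 0.11, adjusted p = 1.39e-15). MpDHN1 (Mp6g07540), a dehydrin gene, was at 47.6 ± 17.2 against 2.86 ± 0.945 CPM (3.63 ± 0.28), and MpLEAL3 (Mp6g02960), MpLEA-like37 and MpLEA-like14 were higher by 3.17 ± 0.26, 3.09 ± 0.23 and 3.03 ± 0.33. Of the desiccation genes, 33 were higher, 11 lower and 25 did not pass (35 and 13 adjusted over the list alone, adjusted p = 3.12e-05, and adjusted p = 0.606 with an estimated correlation). The proton pump gene MpHA18 (Mp3g12400) was at 7.51 ± 1.73 against 49.6 ± 3.07 CPM (-2.59 ± 0.17), and MpPPO38, MpPPO40 and MpKOL3 differed by -3.08 ± 0.16, -2.38 ± 0.14 and -2.24 ± 0.22. MpLOX4 was lower before wounding (-1.93 ± 0.23), and so was MpJAZ (-0.53 ± 0.09). Desaturase and elongase genes gave 0 higher and 14 lower (0 and 14 adjusted over the list alone, adjusted p = 0.00103, and adjusted p = 0.175 with an estimated correlation), with MpFAD11 (Mp5g20700) and MpFAD4 at -0.96 ± 0.07 and -0.45 ± 0.10. With library totals the list's median went from -0.25 to -0.11. Cell cycle and histone genes gave 2 and 13 (2 and 13 adjusted over the list alone, adjusted p = 0.0330, and adjusted p = 0.787 with an estimated correlation), with a median of -0.24 that became -0.105 with library totals. Peroxidases gave 40 higher and 31 lower (41 and 32 adjusted over the list alone).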

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

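The tests of the kept share outside a list, of the constant added before the log and of relabelled libraries with genotype means removed were chosen only after the result was seen. In Mpcoi1 against Tak-1, 1001 genes differed in response. Relabelling genotypes within mock and within wounded libraries gave as many in 7 of 100 draws, the real one included, with 1793 in the highest other. For Mpdes6fad5 against Tak-1 (1961 genes) it was 10 of 100, with 4313 in the highest other, and for Mpdes6fad5 against Mpcoi1 (2419 genes) 7 of 100, with 4168. By these shares chance cannot be excluded. The other draws with as many genes, 6, 9 and 6, all exchanged at least 2 more libraries in one treatment than in the other, which puts the difference between genotypes into the response; such a draw points to that structure of the samples. With each genotype's mean removed, 1 of 100 draws gave as many in each comparison, and the highest others gave 304, 727 and 634.

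For comparisons of 3 libraries with 3, there are 10 splits, too few for a share under 0.05. In each, 1 split, the real one, gave as many genes. The real counts were 7480, 6999 and 7533 for the wound responses of Tak-1, Mpcoi1 and Mpdes6fad5 and 881 and 5016 for mock Mpcoi1 and Mpdes6fad5, and the highest other split gave 0 in each by limma, with 182 to 2008 genes at an unadjusted p under 0.05. The count of 881 ran from 363 to 1407 when 1 library was left out, without mock Mpcoi1 replicate 2 and without wounded Tak-1 replicate 3.

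A first pattern was the smaller response of oxylipin genes in Mpcoi1, where the lipoxygenase and CYP74 list had a median difference of -0.75. In Tak-1, 6 of the 17 members rose and 6 fell, with a median response of 0.12. In Mpcoi1, 2 rose and 10 fell, with a median of -0.67 (camera, adjusted p = 0.0165, and adjusted p = 0.274 with an estimated correlation). The list difference thus held falls in Mpcoi1 as well as lost rises. Weaker wounding of the mutant plants would lower all responses alike, but the median kept share was 0.891 over the 1554 genes outside the list and 0.0947 over the 8 members changed at least 2-fold in Tak-1. Of the 17 members measured, 16 had no listed neighbour, with a median of -0.70. This cannot decide on reads shared between neighbouring copies. Nearly all members stayed in, so the median could hardly move, and neighbours outside the list were not examined. Reads shared with copies elsewhere in the genome were not tested. Dependence of these genes on the receptor is a candidate explanation, found and tested on the same libraries. No second allele was used here.

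A second pattern was the larger response of desiccation genes in Mpdes6fad5, with a median difference from Tak-1 of 0.44. Stronger wounding of the double mutant was argued against by a median kept share of 0.892 outside the list and 1.2 over its 31 members changed at least 2-fold in Tak-1, and a few libraries by a lowest median of 0.34 when 1 wounded library was left out. The constant added before the log remains open: with 0.1 CPM the adjusted p was 0.115, with the deposited values 0.150 and with voom 0.526, against a range of 4.33e-10 to 0.554 over all alternatives. Of the 57 LEA genes, 28 were already higher in mock Mpdes6fad5 than in mock Tak-1 and 7 were lower, with a median log2 difference of 0.44 per gene. The median mock level over these genes was 8.23 CPM, against 1.58 CPM in Tak-1. For a gene with a higher mock level, the same ratio gives a larger change of log2(CPM + 1). The larger response may therefore reflect the scale for such genes. Summed CPM of the 57 LEA genes, which involves no constant, went from 1505 ± 111 to 3504 ± 400.1 in Mpdes6fad5. In Tak-1 it went from 1591 ± 69.6 to 2276 ± 128. A sum also rises more where the inducible genes start from higher mock levels, even at equal ratios per gene. It therefore cannot decide whether the scale accounts for the whole, and a biological difference stays open.

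A further pattern was the larger distance of mock Mpdes6fad5 than of mock Mpcoi1 from Tak-1, 5016 against 881 genes, or 5406 against 1407 without wounded Tak-1 replicate 3. Female double-mutant plants would lack V-linked transcripts, but the 33 expressed V-linked genes had a median difference of 0.048. The ratio of the counts stayed at 5.36 or above under 3 other scalings, so the scaling of the libraries did not account for it. Growth, tissue taken and line history were not tested and could also differ between lines. An effect of the desaturase mutations stays a hypothesis.

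Other list differences were tested by camera as differences of response, and none of those in this paragraph was called with an estimated correlation. Against Tak-1, Mpcoi1 had medians of 0.26 for desiccation genes, -0.11 for bHLH genes, -0.26 for dirigent and polyphenol oxidase genes and -0.15 for phenylpropanoid genes, the last not called with voom (adjusted p = 0.0513) or without mock replicate 3 (adjusted p = 0.0586) or wounded replicate 3 (adjusted p = 0.0995) of Tak-1. With an estimated correlation their adjusted p were 0.787, 0.410, 0.270 and 0.510. Mpdes6fad5 had -0.53 for lipoxygenase and CYP74 genes against Tak-1 (0.270 with an estimated correlation). Against Mpcoi1 it had 0.30 for that list, 0.15 for bHLH genes, 0.52 for dirigent and polyphenol oxidase genes, 0.24 for phenylpropanoid genes, 0.15 for terpenoid genes and -0.084 for glutathione genes, with adjusted p of 0.270, 0.510, 0.270, 0.364, 0.274 and 0.657 with an estimated correlation. Terpenoid genes were not called without a filter (adjusted p = 0.0588), nor glutathione genes with quantile normalization (adjusted p = 0.0531). Calcium signalling genes, at -0.29, were not called at a mean of at least 5 CPM (adjusted p = 0.0599), without wounded Mpcoi1 replicate 2 (adjusted p = 0.0691) or wounded Mpdes6fad5 replicate 2 (adjusted p = 0.0642), nor with an estimated correlation (0.657). Desiccation genes, at 0.32, had a median of 0.0093 with a constant of 0.1 CPM or with deposited values (adjusted p = 0.970 and 0.917, the test's direction reversed, in a range of 2.13e-05 to 0.970 over all alternatives). They were not called without any 1 of 5 libraries: Tak-1 wounded replicate 3 (0.0508), Mpcoi1 wounded replicate 3 (0.123), Mpdes6fad5 mock replicates 2 (0.0676) and 3 (0.0963) and Mpdes6fad5 wounded replicate 3 (0.180). With an estimated correlation their adjusted p was 0.802. Cytochrome P450 and glycosyltransferase genes, at 0.13 and at -0.01 with quantile normalization (adjusted p = 0.0607), were not called with a constant of 5 CPM (0.0522), without a filter (0.0801) or without any 1 of 6 libraries: Mpcoi1 mock replicate 1 (0.0621), Mpcoi1 wounded replicates 1 (0.0595) and 3 (0.0946), Mpdes6fad5 mock replicates 2 (0.0741) and 3 (0.0719) and Mpdes6fad5 wounded replicate 1 (0.0510). With an estimated correlation their adjusted p was 0.517.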

How the results depend on the processing

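The alternatives of library totals, deposited values and voom, and their tests, were chosen after the data were seen; the cause of a change was not tested unless stated. A planned count model (edgeR, DESeq2) was not run. The deposited unit is log2, but whole reads were recovered, so the unit did not prevent such a model. The results were thus not tested with it, and voom on recovered reads took its place. A 2-fold minimum lowered the counts by construction, to 1562, 1286 and 1697 for the wound responses of Tak-1, Mpcoi1 and Mpdes6fad5, 305 and 343 for Mpcoi1 and Mpdes6fad5 against Tak-1, 538 for Mpdes6fad5 against Mpcoi1, and 136 and 570 for mock Mpcoi1 and Mpdes6fad5. Leaving out 1 library gave 363 (without mock Mpcoi1 replicate 2) to 1407 (without wounded Tak-1 replicate 3) genes for mock Mpcoi1, against 881. The other counts stayed within 1.5 times the main ones when 1 library was left out: 6686 to 7580, 6147 to 7292 and 6789 to 7840 for the wound responses, 770 to 1176, 1494 to 2826 and 1874 to 2855 for the differences and 4061 to 5406 for mock Mpdes6fad5. With the replicate number as a replicate block the counts were 7441, 6969, 7532, 991, 1969, 2466, 911 and 5030, with 47 list calls. After group means were removed, 0 of 9 pairs of mock and wounded libraries of one genotype and number correlated above 0.1 (-0.33 to 0.0623), nor did most of all 45 same-number pairs: 10 did, among them wounded Tak-1 with wounded Mpcoi1 (0.163, 0.199 and 0.555), where a pair of unlike number reached 0.464. Of 18 libraries, 10 were nearer to their own number. The share kept in Mpcoi1, 0.754, became 0.789 with a mean of at least 5 CPM and 0.785 with genes chosen on 2 replicates. The share kept in Mpdes6fad5, 0.939, became 0.906 with a constant of 5 CPM, 0.969 with quantile normalization, 0.975 with genes chosen on 2 replicates, and 0.907 (without wounded Tak-1 replicate 3) to 0.944 with 1 library left out. Of 200 list tests 43 were called, 4 with an estimated correlation and 115 with fry, which tests against no change instead of against other genes. The desiccation list in Mpdes6fad5 against Mpcoi1 (adjusted p = 0.0380) changed direction and lost its call with a constant of 0.1 CPM (0.970), deposited values (0.917) and voom (0.617), in a range of 2.13e-05 to 0.970. It was not called at a mean of at least 5 CPM (0.234) or with fry (0.0581). Other list calls were lost in part: AP2/ERF genes in Tak-1 with 0.1 CPM (0.0549), deposited values (0.0544) and voom (0.0550), MAP kinase and phosphatase 2C genes in Tak-1 with quantile normalization (0.0804), and cell wall genes in Tak-1 (0.0742) and Mpdes6fad5 (0.0522) at a mean of at least 5 CPM. Of 253 called results of 167 named genes, 187 were the same under every one of the 13 alternatives and 18 left-out libraries that gave a value. Of these 187, 23 had no value at a mean of at least 5 CPM, a filter that removed 41 of the 253. Calls were lost under at least 1 of them for 64 results, and 5 results changed sign. The 13 alternatives include the 2-fold minimum, which by construction ended the calls of 36 results with smaller folds. Among results at low CPM in Mpdes6fad5 against Tak-1, voom ended the calls of MpWRKY6 (2.17), MpCupin36 (-3.64), MpDIR61 (-3.06) and MpDIR65 (-2.45) at larger folds than the main ones, and those of MpLEA-like28 (1.35), MpLEA-like26 (1.23), MpLEA-like27 and MpPOD19 (-0.38) at smaller ones. MpPOD19 was not called with 0.1 CPM (-1.24) or deposited values (-1.18) either, nor MpLEA-like27 (1.34 and 1.33). In Mpcoi1 against Tak-1, MpLEA-like37 was not called with voom (2.28), and MpPPO38 with 0.1 CPM, deposited values (1.17) or voom (1.01). The 5 that changed sign were differences of Mpdes6fad5 against Tak-1 at low CPM: with voom MpLEA-like39 gave -0.072, MpLEA-like34 -1.47, MpLEA-like40 -0.15 and MpPPO31 0.99, and MpLEA-like36 gave -0.61 with 0.1 CPM, -0.76 with deposited values and -2.36 with voom. With 0.1 CPM and with deposited values, MpLEA-like34 (0.23 and 0.090), MpLEA-like40 (0.67 and 0.59) and MpPPO31 (-0.56 and -0.47) kept their sign but were not called.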

Other observations

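The comparison of Tak-1 genes that responded less in Mpcoi1, and its tests, were chosen only after the main results were seen. Of 31 auxin genes, 4 responded more and 7 less in Mpcoi1 than in Tak-1, and 20 did not pass (5 and 9 adjusted over the list alone, adjusted p = 0.0501, and adjusted p = 0.510 with an estimated correlation). Of 42 terpenoid genes, 1 responded more and 6 less, and 35 did not pass (1 and 6 adjusted over the list alone, adjusted p = 0.101, and adjusted p = 0.510 with an estimated correlation). Neither list was called. MpPIN3 (Mp6g07950), of the PIN auxin carriers, rose by 3.40 ± 0.17 in Tak-1 and 2.08 ± 0.17 in Mpcoi1, a difference of -1.32 ± 0.25. MpSAUR10 (Mp1g27960) rose by 2.08 ± 0.13 in Tak-1 and gave -0.21 ± 0.13 in Mpcoi1, a difference of -2.29 ± 0.18. MpHMG (Mp2g07980), for the HMG-CoA reductase of the mevalonate pathway, rose by 1.12 ± 0.08 in Tak-1 and 0.86 ± 0.08 in Mpdes6fad5, and differed by -1.34 ± 0.11 in Mpcoi1. The homeobox gene MpC1HDZ (Mp3g02320) rose by 1.43 ± 0.11 in Tak-1 and differed by -1.15 ± 0.16 in Mpcoi1. It belongs to the list of oil body cells, of whose 5 measured genes 0 responded more and 1 less in Mpcoi1 than in Tak-1, and 2 more and 0 less in Mpdes6fad5 than in Mpcoi1, with the same counts when adjusted over the list alone. The list was not called (adjusted p = 0.176 and 0.270, and adjusted p = 0.510 and 0.554 with an estimated correlation), but fry, which tests against no change, gave 9.43e-05 and 4.08e-05. The share of oil body cells in the tissue was not measured here. The MYB gene MpR2R3-MYB20 (Mp4g21790) rose by 1.14 ± 0.13 and differed by -1.63 ± 0.19. The desaturase gene MpFAD11 rose in Tak-1 and fell with -0.55 ± 0.07 in Mpcoi1.

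Some chaperone genes responded less in the double mutant. MpHSP90-1 (Mp1g26610) went from 346 ± 21.1 to 841 ± 36.6 CPM in Tak-1 and from 323 ± 17.7 to 416 ± 23.1 CPM in Mpdes6fad5, a difference of -0.92 ± 0.10 (adjusted p = 1.17e-05). Of the 6 heat shock genes measured, 3 responded less and 1 more (4 and 1 adjusted over the list alone), and the list was not called (adjusted p = 0.0673, and adjusted p = 0.510 with an estimated correlation). MpR2R3-MYB5 (Mp8g11870) rose by 1.22 ± 0.12 in Tak-1 and differed by -0.93 ± 0.17 in Mpdes6fad5. Some clock and calcium genes rose in all 3 genotypes: MpGI (Mp1g13750), the GIGANTEA gene, rose by 1.34, 1.57 and 1.15 in Tak-1, Mpcoi1 and Mpdes6fad5, and the calmodulin-like gene MpCML42 (Mp6g18000) by 3.24, 3.54 and 3.24.

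A further comparison asked whether the double mutant loses what the receptor mutant loses. Of the 333 genes that rose at least 2-fold in Tak-1 and responded less in Mpcoi1, 322 rose in Mpdes6fad5 and 111 (33.3%) responded less there than in Tak-1. Of the 808 other rises, not called as different in Mpcoi1, 173 (21.4%) responded less. The mean response of the 333 genes was 2.18 in Tak-1, 1.86 in Mpdes6fad5 and 0.55 in Mpcoi1, the last low by the choice of the genes. Because the genes were chosen on the Tak-1 and Mpcoi1 libraries, the share kept in Mpdes6fad5 was also measured against a Tak-1 replicate held out of the choice, at 0.862, 0.925 and 0.851, against 1.06, 1.01 and 0.981 for the other rises. With each held-out replicate the share kept was lower for these genes than for the other rises, a difference that was not tested. The lowest share, 0.851, argues against a loss as large as that in Mpcoi1. A candidate explanation is that the double mutant still makes enough ligand for most of the response of these genes at this time. No ligand was measured here, so this stays a hypothesis.

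Over the 13220 tested genes, the responses of Tak-1 and Mpcoi1 had a Pearson correlation of 0.839, those of Tak-1 and Mpdes6fad5 0.868 and those of the mutants 0.801. Genes are not independent replicates, so these values carry no test, and no library entered more than 1 of these responses.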
